A study of Mus musculus with 15 samples.

How the data were processed

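The series holds 15 2-colour Agilent expression arrays, 1 array per sample and 3 samples in each of 5 groups. Per the labels' protocols, amplified RNA of each sample was labelled with Cy3 and hybridised against a Cy5-labelled reference pool of prostate, testis, liver and kidney RNA, in the same dye orientation on every array. The groups are benign prostate epithelium without Cre (labelled as microdissected), the Pten-heterozygous lines P8 and P2, and the Pten-null lines CaP8 and CaP2. The titles name the lines PTEN-P8, PTEN-P2, PTEN-CaP8 and PTEN-CaP2, shortened here. The descriptions call the samples biological replicates, but no label says whether they came from separate cultures or animals, so they may be technical, and every p-value measures only the spread between these samples. The descriptions of CaP8 replicate 3 and CaP2 replicate 3 both carry the number 1, and the number in the title was followed. The labels give the same culture protocol for all samples, the microdissected ones included.

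Spot and local background intensity values were read from the scanner files, made with Agilent Feature Extraction 10.7.3.1 per the file headers, and carry no normalization. The processed intensity columns of the same files are background-subtracted, detrended and dye-normalized by a linear and lowess fit, per the file headers. The scanner files' log10 ratio of Cy5 over Cy3 comes from those processed signals, per the file headers. The deposited value table holds log2 values that equal the log2 ratio of Cy3 over Cy5 processed signals, found by setting each column against its array's scanner values (largest difference on any array 4.9e-09). Its scale, centring and direction are thereby settled, its column medians ran from 0.459 to 0.660, and the rule that left 31.5 to 40.4% of its cells blank is not stated. Probe positions are those of the mouse build mm8 named in the file headers.

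From the unprocessed intensities, both channels were background-corrected by normexp with an offset of 50, and loess normalization within each array gave the log2 ratio of sample over reference. Each array had 45190 spots, of which 1425 were control spots. Spots of 1 probe were averaged, leaving 42204 probes. An accession table named 23583 of the probes, 9852 were named by symbol through the same table, and 8769 kept the name in the file. For a gene with several probes the probe with the highest mean intensity over all 15 arrays was used. A gene was tested if Cy3 was well above background on at least 3 arrays of the fit. A spot with outlier marks on more than 1 array was left out. No spot was saturated.

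Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values for genes come from limma. The 4 lines were fitted together on 12 arrays, for CaP8 against P8, CaP2 against P2, the mean of both pairs, and the difference between pairs (CaP8 minus P8, less CaP2 minus P2). Comparisons with benign epithelium used all 15 arrays. Where a probe was not well above background on any array of a group, the text gives a bound as "at least N-fold", from Cy3 values after loess and Aquantile normalization, with the dimmer group set at the lowest signal that was well above background or at its own value, whichever was higher. These bounds rest on the Cy3 channel and can exceed the fitted fold of the ratio. Without dye swaps they are open to dye bias.

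The named genes were fixed by a rule before the data were examined. It takes Pten, Csf1 and Il1b, the 10 largest rises and 10 largest falls with non-overlapping replicates in CaP8 against P8, CaP2 against P2 and the mean of the lines against benign, the 10 largest shared changes and up to 5 opposite ones, the 5 largest differences each way, and from each fixed list up to 4 members with the lowest adjusted p and members that went against the rest. The 23 lists held 488 genes, of which 479 were on the array: FOXO targets, myeloid chemoattractants and growth factors, immune suppression genes, interferon response, MHC class I presentation, androgen response and prostate secretion, DNA replication, mitosis, glycolysis and hypoxia, cholesterol synthesis, ER chaperones and secretory stress, p53 targets, immediate early genes, and markers of luminal, basal, mesenchymal, smooth muscle, fibroblast, leukocyte, endothelial and erythroid cells, seminal vesicle secretion and the reference pool's tissues. Each was tested against all other genes with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists. A higher adjusted p with the estimated correlation need not mean a correlation above the preset one. The immune suppression list in CaP8 against P8 had an estimated correlation of 0.00233, and its adjusted p by camera still went from 0.0192 to 0.0902.

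The 15 arrays lay on 6 slides scanned on 2 days. Benign epithelium filled slide 1, so that slide could not be fitted as a fixed block there. P8 replicates 1 and 2 lay on slide 2, P8 replicate 3 with all CaP8 arrays on slide 3, CaP2 replicate 1 on slide 4, P2 replicates 1 and 2 with CaP2 replicates 2 and 3 on slide 5, and P2 replicate 3 on slide 6, scanned on day 2. Only slides 3 and 5 hold both lines of a pair, so with slide as a fixed block the fold change of a pair is the one within that slide, a single estimate that rests on 1 P8 array in pair 8 and on 2 arrays of each line in pair 2. Alternatives were the processed signals, no background subtraction, Aquantile normalization, the Cy3 channel alone, other filters, the mean over probes, a trended robust variance, the deposited table, other sets of arrays in the fit, slide and replicate number as blocks, and leaving out each array. Between 54.6 and 72.1% of spots had Cy3 well above background, and the number of arrays limits the precision. The fit was tested on simulated data with independent normal noise, no slide effect and 200 changed genes among 19876. Of genes changed by 0.5, 1 and 2 log2 units in CaP8 against P8, 57.8, 84.6 and 100% were recovered, and 5.78% of the calls were false. For the difference between pairs 32.3, 71.4 and 97.1% were recovered, and 5.56% of the calls were false. The real data need not meet these conditions, so their share of false calls was not measured. No reference genome was at hand, so no probe was placed in an exon.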

Results

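Gene expression was measured in 12 samples of 4 prostate cell lines from mice with a conditional Pten allele and in 3 samples of benign prostate epithelium. P8 and P2 are heterozygous for Pten, the lipid phosphatase that opposes PI3K signalling, and CaP8 and CaP2 are labelled Pten null. Each group had 3 arrays. Replicates of 1 group correlated at 0.989 or more over genes. P8 correlated with CaP8 at a mean of 0.992 and P2 with CaP2 at 0.980, while benign epithelium correlated with the lines at 0.874 to 0.889. Means within the lines were 0.993 in P8, 0.998 in CaP8, 0.994 in P2 and 0.992 in CaP2. The P8 replicates were thus little closer to each other than to CaP8. Median Cy3 intensity per array ran from 232 to 373.

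Pten was lower in each null line than in the heterozygous line of the same number, and all 3 arrays of each null line kept Pten signal well above background. The log2 ratio of Pten to the reference (probe A_51_P275350, chromosome 19, 32884017 to 32885858 in mm8) was 0.24 ± 0.08 in benign epithelium, -0.90 ± 0.01 in P8, -1.32 ± 0.03 in CaP8, -0.26 ± 0.12 in P2 and -0.66 ± 0.04 in CaP2 (SD, n = 3 each). By limma, Pten fell by 0.42 log2 units in CaP8 against P8 (SE 0.058, adjusted p = 0.000897) and by 0.40 in CaP2 against P2 (SE 0.058, adjusted p = 0.000309). The difference between the pairs was -0.017 (adjusted p = 0.914). With slide as a block, which is the value within slide 3 for CaP8 and within slide 5 for CaP2, Pten fell by 0.41 and 0.42, and the first rests on 1 P8 array. A second probe, A_52_P24843, fell by 0.53 in CaP8 and by 0.30 in CaP2. The third, A_52_P121155, had -0.21 and -0.26 and did not pass the threshold. The mean ratio of the second probe was -0.827 in P8, -1.354 in CaP8, -0.904 in P2 and -1.207 in CaP2. That of the third was 1.485, 1.273, 1.452 and 1.192 in the same order. The order of the lines across pairs thus depends on the probe. Where the probes lie relative to the deleted part of Pten is not given, so these values do not check the genotype labels.

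Csf1, the macrophage colony-stimulating factor, had nearly the same ratio to the reference within each pair, with differences of 0.035 in CaP8 against P8 (adjusted p = 0.830) and -0.084 in CaP2 against P2 (adjusted p = 0.408). Read from the Cy3 channel alone, Csf1 fell by 0.62 in CaP8 (adjusted p = 0.00298) and by 0.52 in CaP2 (adjusted p = 0.00302), so the call depends on the use of the reference channel. Against benign epithelium, Csf1 rose by 0.95 in the mean of the lines as a ratio and by 2.28 in Cy3 alone. Il1b, the gene of interleukin-1 beta, was not well above background on any of the 15 arrays.

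**Figure D1:**
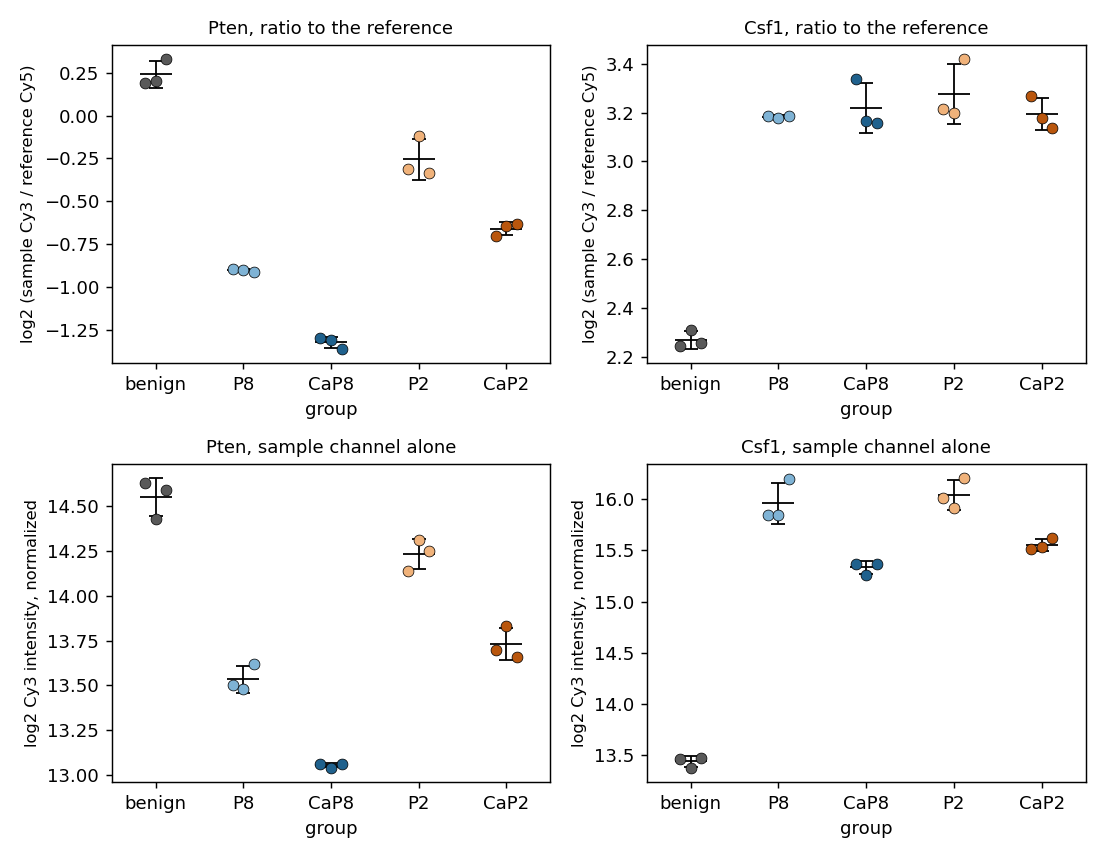
Pten and Csf1 on each array by group, as log2 ratio of sample over reference (top) and as normalized log2 Cy3 intensity (bottom). Points are arrays, and bars are the mean and SD of 3. Pten is shown by probe A_51_P275350 only. Pten lies lower in CaP8 than in P8 and lower in CaP2 than in P2 on both scales, while Csf1 differs within the pairs in the Cy3 channel alone.

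CaP8 against P8 asks what differs between a Pten-null line and the heterozygous line of the same number. ER chaperones and secretory stress genes rose in CaP8, with 12 of 22 measured members up and none down, among them Xbp1, a transcription factor of the unfolded protein response (0.75, SE 0.069), and Chac1 (0.70, SE 0.056). Of 28 glycolysis and hypoxia genes 12 rose, among them Bnip3 (0.77) and the pyruvate dehydrogenase kinase Pdk1 (0.50), while Hk2 (-0.42) and Egln1 (-0.18) fell. Immediate early genes fell in 8 of 22 cases, among them Ccn1 (-1.09) and Ccn2 (-1.01), against rises of Atf3 (0.69) and Klf4 (0.30). Camera gave the ER list an adjusted p of 2.01e-07, which held at 0.00518 with an estimated correlation. The glycolysis list passed at 1.58e-06 and the immediate early list at 0.00125, and both had an adjusted p = 0.0902 with an estimated correlation. The counts adjusted over the list alone were 12 ER genes up, 13 glycolysis genes up and 2 down, and 11 immediate early genes down and 2 up. With slide as a block, which takes the pair's values from slide 3 and its 1 P8 array, the list medians were 0.18, 0.19 and -0.17.

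Extracellular matrix and fibroblast genes moved in both directions in this pair. Of 30 mesenchymal markers 11 rose, among them Col3a1 (1.27), periostin Postn (1.16) and the gelatinase Mmp2 (1.03), and 4 fell, namely Mmp3 (-1.16), Cdh2 (-0.39), Col5a2 (-0.22) and Cdh11 (-0.22). The list had an adjusted p = 0.00431, and an adjusted p = 0.287 with an estimated correlation. Of 13 fibroblast markers 5 rose, including Dpt (0.96) and decorin Dcn (0.65), and Mfap5 (-0.51) and Fbln1 (-0.48) fell, with adjusted p = 0.0121 and adjusted p = 0.0902 with an estimated correlation. Of 20 p53 targets 5 rose, including Trp53inp1 (0.51) and the cell cycle inhibitor Cdkn1a (0.30), and Plk2 fell by 0.30 (list adjusted p = 0.00431, and adjusted p = 0.0902 with an estimated correlation). Adjusted over the list alone, 11 mesenchymal markers rose and 5 fell, 6 fibroblast markers rose and 2 fell, and 6 p53 targets rose and 1 fell. The fibroblast list no longer passed with slide as a block (adjusted p = 0.135, median 0.085), while the mesenchymal list (0.000637, median 0.20) and the p53 list (0.0336, median 0.084) did. In the Cy3 channel alone the fibroblast median went from 0.145 to 0.081 and the mesenchymal median from 0.098 to 0.062.

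Among immune genes, 5 of 14 immune suppression genes rose, including Tgfb3 (0.41) and Lgals9 (0.27), with none down. Of 17 MHC class I presentation genes 7 rose, among them the peptide transporter Tap2 (0.91), and Erap1 (-0.34) and H2-K1 (-0.16) fell. The lists had adjusted p = 0.0192 and 0.0396, and adjusted p = 0.0902 and 0.287 with an estimated correlation. Of 22 myeloid chemoattractants and growth factors, 5 rose, including Il6 (1.46) and Ccl5 (1.07), and 3 fell, including Cxcl12 (-0.91). Ldlr fell by 0.27 as 1 of 4 falling cholesterol genes of 25 (list adjusted p = 0.0483, and adjusted p = 0.115 with an estimated correlation). Adjusted over the list alone, 5 immune suppression genes rose, 7 MHC class I genes rose and 2 fell, 5 myeloid genes rose and 5 fell, and 5 cholesterol genes fell and 1 rose. The MHC class I list (adjusted p = 0.0693, median 0.20) and the cholesterol list (adjusted p = 0.301, median -0.071) no longer passed with slide as a block, the immune suppression list did (0.0184, median 0.25), and the myeloid median was -0.017.

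The largest rises in CaP8 were Ostn (3.04), Krt33a (2.67), Agtr2 (2.42, at least 4.2-fold), Lrrc17 (2.38), Crabp2 (2.34, at least 4.42-fold), Nefl (1.80), the haemoglobin gene Hba-a1 (1.77), Kirrel3 (1.72), As3mt (1.65) and Avil (1.64). The largest falls were the BMP antagonist Grem2 (-2.81, at least 7.48-fold), Tll1 (-2.41), cholecystokinin Cck (-2.33), Brinp3 (-2.19), Cd24a (-1.84), Nsg1 (-1.81), Ccbe1 (-1.69), the acute-phase gene Saa3 (-1.64), Mgp (-1.52) and Kcnab1 (-1.51). By the rule, these were picked only from genes past the threshold with replicates that did not overlap. In total 2736 of 19963 genes passed, 1454 up and 1282 down, and 127 changed at least 2-fold. The balance of rises and falls was 1809 to 1126 with the processed signals, 1086 to 705 with the deposited table and 2811 to 3057 with slide as a fixed block. The count was 5868 with slide as a fixed block, 5190 with slide as a random block and 5597 on slide 3 alone, and the fixed block and slide 3 share their fold changes, which rest on 1 P8 array. It was 1784, 1582 and 1647 without CaP8 replicate 1, 2 and 3. Of the named genes, Egln1, Cdh11 and H2-K1 did not pass with slide as a fixed block (adjusted p = 0.146, 0.102 and 0.102), and Egln1, Cdh2, Cdh11, Klf4, Erap1, H2-K1, Ldlr, Plk2 and Lgals9 did not pass in the Cy3 channel alone.

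CaP2 against P2 asks the same in the other pair. Cholesterol synthesis genes were higher in CaP2 than in P2 in 24 of 25 cases, by a median of 0.83 log2 units, among them Tm7sf2 (1.75, SE 0.062), the HMG-CoA synthase Hmgcs1 (1.24, SE 0.055), Fdps (1.21) and Msmo1 (1.09). Against benign epithelium, 20 of 25 of these genes were lower and 2 higher in P2, with a median of -0.68, and the medians of P8, CaP8 and CaP2 were 0.23, 0.34 and 0.19. The list passed there in P2 (adjusted p = 1.44e-05, and adjusted p = 0.0592 with an estimated correlation) and not in P8, CaP8 or CaP2 (0.324, 0.446 and 0.38). Glycolysis and hypoxia genes rose in 21 of 28 cases, among them Pdk1 (1.58), Bnip3 (1.18) and Ankrd37 (1.03), while adrenomedullin Adm fell by 1.64. ER chaperones and secretory stress genes rose in 15 of 22 cases, including Xbp1 (0.89) and Pdia6 (0.81), and Atf4 fell by 0.24 (camera, list adjusted p = 3.64e-06). The cholesterol list (adjusted p = 2.57e-16) and the ER list held with an estimated correlation, at 0.00035 and 0.00629. The glycolysis list passed at 6.58e-08, with adjusted p = 0.067 with an estimated correlation. When adjusted over the list alone, 24 cholesterol genes were higher, 22 glycolysis genes rose and 2 fell, and 15 ER genes rose and 1 fell. With slide as a block, which takes the pair's values from slide 5, the medians of these lists were 0.88, 0.48 and 0.40.

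Interferon response genes rose in 17 of 26 cases in CaP2, among them the ubiquitin-like modifier Isg15 (1.75), Oasl2 (1.22) and Ifit3 (1.11), and Ifitm3 fell by 0.20. Mitosis genes fell in 16 of 30 cases, including cyclin Ccnb1 (-0.48) and the kinase Aurka (-0.37), with Ccnb2 (0.24) and Foxm1 (0.21) up. P53 targets fell in 11 of 20 cases, among them the cell death genes Pmaip1 (-0.81) and Fas (-0.66), with Bbc3 (0.40) and Gdf15 (0.31) up. The interferon list had adjusted p = 2.2e-05, and adjusted p = 0.067 with an estimated correlation. The mitosis and p53 lists had adjusted p = 5.76e-05 and 0.000537, and adjusted p = 0.05 for both with an estimated correlation. Counts adjusted over the list alone were the following: 18 interferon genes rose and 1 fell, 16 mitosis genes fell and 2 rose, and 12 p53 targets fell and 2 rose. Their medians with slide as a block were 0.45, -0.20 and -0.24.

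Basal epithelial markers rose in 8 of 17 cases in CaP2, including laminin Lamc2 (1.21) and integrin Itgb4 (0.91), and Snai2 fell by 0.40. Of 22 myeloid chemoattractants and growth factors 10 fell, including the prostaglandin synthase Ptgs2 (-2.13) and Cxcl12 (-1.31), and 4 rose, including Il34 (1.42) and Ccl5 (1.05). MHC class I presentation genes rose in 9 of 17 cases, including Calr (0.87) and H2-T23 (0.56), while Tap1 (-0.48) and Erap1 (-0.23) fell. The adjusted p was 0.00469 for the basal list and 0.015 for the other two, and each had an adjusted p = 0.213 with an estimated correlation. Adjusted over the list alone, 9 basal markers rose and 1 fell, 10 myeloid genes fell and 4 rose, and 9 MHC class I genes rose and 2 fell. The myeloid list no longer passed with slide as a block (adjusted p = 0.0503, median -0.12), while the basal list (0.0176, median 0.24) and the MHC class I list (0.00723, median 0.24) did. In the Cy3 channel alone the basal median went from 0.228 to 0.141.

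The largest rises in CaP2 were the keratin Krt19 (3.96), Aspn (2.89), Esm1 (2.86), Itm2a (2.73), Cbr2 (2.71), Crip1 (2.69), Car8 (2.64), Dpt (2.58), Isg20 (2.51) and Hopx (2.45). The largest falls were Gdf10 (-4.25), H2-M9 (-4.18), Akr1c18 (-3.66), the contractile genes Cnn1 (-3.62) and Tagln (-3.47), Brinp3 (-3.52), Lce1i (-3.52), Npy1r (-3.43), Pi15 (-3.43) and the Wnt antagonist Sfrp1 (-3.42). In total 7198 of 19963 genes passed the threshold, 3678 up and 3520 down, and 649 changed at least 2-fold. Falls outnumbered rises with the processed signals (3406 to 3363), the mean over all probes (3416 to 3010), the deposited table (2326 to 2106) and without P2 replicate 2 (3155 to 3147). The count was 7506 with slide as a fixed block and 6278 on slide 5 alone, and both share their fold changes, which rest on 2 arrays of each line. Of the named genes, Gdf15 did not pass with slide as a fixed block (adjusted p = 0.061), and Aurka, Foxm1, Tap1 and Erap1 did not pass in the Cy3 channel alone.

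**Figure D2:**
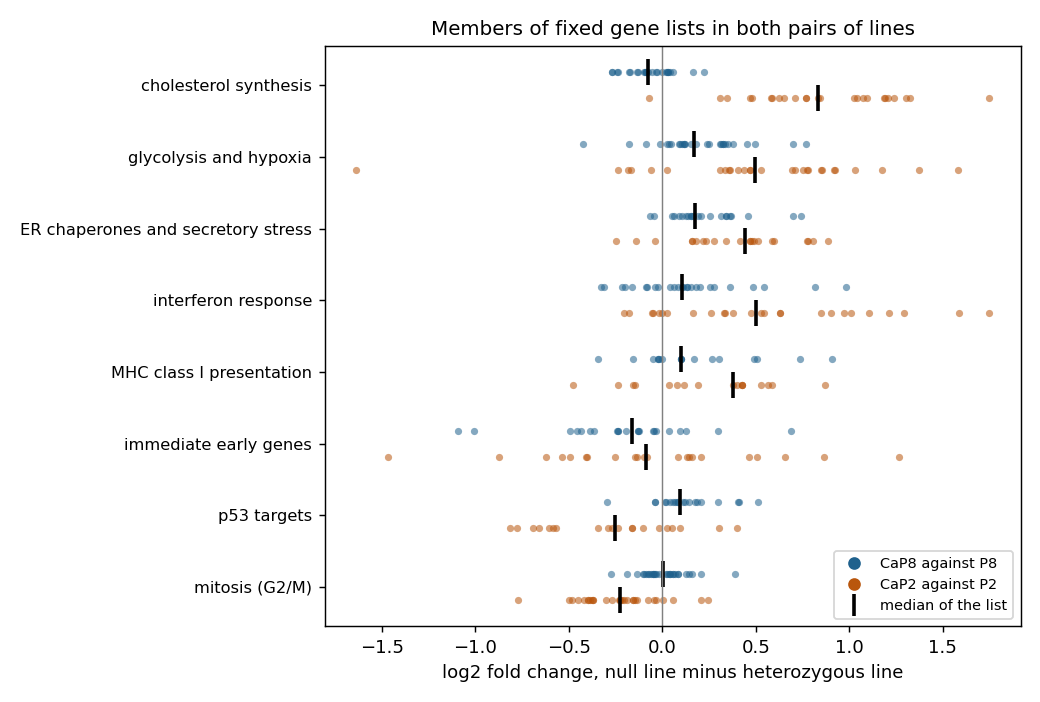
Log2 fold change of each measured member of 8 fixed gene lists, null line minus heterozygous line, in CaP8 against P8 (blue) and CaP2 against P2 (orange). Each point is a gene and each black bar the list's median. The median of the cholesterol list is 0.83 in CaP2 against P2 and -0.076 in CaP8 against P8.

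Of genes past the threshold in both pairs, 922 rose in both, 762 fell in both and 300 went in opposite directions, where independent lists would give 267.9, 226.1 and 492.6. Over all 19963 genes the fold changes of the pairs correlated across genes at r = 0.333 and rho = 0.283, genes not being independent replicates. Shared changes were ranked by the effect in the pair where it was smaller, and the values given are means of both pairs. By this ranking the largest shared rises were Agtr2 (2.44), Lrrc17 (2.38) and Htra1 (1.77). The largest shared falls were Grem2 (-2.96), Brinp3 (-2.85), Saa3 (-2.45), Ccbe1 (-2.35), Tll1 (-2.33), Nsg1 (-1.70) and Mgp (-1.50). A gene with unlike effects in the pairs could have a larger mean and not be named here. Xbp1 (0.82), Pdk1 (1.04), Bnip3 (0.97) and Ccl5 (1.06) rose and Cxcl12 (-1.11) fell in the mean of both pairs. The opposite changes named by the rule were those of Pi15, Il6, Adamts3, Syt13 and Spry3, which rose in CaP8 and fell in CaP2. Il6, for example, rose by 1.46 in CaP8 and fell by 2.97 in CaP2. By limma, 6732 genes passed in the mean of both pairs, 3480 up and 3252 down, and 8111 passed with slide as a fixed block, 3976 up and 4135 down. With the mean over all probes, 2899 were up and 3019 down.

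The null-against-heterozygous effect differed between the pairs most clearly for cholesterol synthesis. The effect was lower in pair 8 than in pair 2 for 22 of 25 cholesterol genes, including Tm7sf2 (-1.99) and Hmgcs1 (-1.42). By camera the list had an adjusted p of 1.08e-21, or 0.000119 with an estimated correlation. P53 targets differed the other way in 11 of 20 cases, including Pmaip1 (0.92) and Fas (0.86), with a list adjusted p of 7.19e-06, or 0.0221 with an estimated correlation. Interferon (0.00019), glycolysis (1.24e-05) and mitosis (6.29e-05) lists differed too by adjusted p, with adjusted p = 0.134, 0.134 and 0.0644 with an estimated correlation. Adjusted over the list alone, the effect in pair 8 was lower for 22 cholesterol genes, and higher for 11 p53 targets and lower for 2. It was lower for 13 interferon genes and higher for 2. For glycolysis it was lower for 19 genes and higher for 2, and for mitosis higher for 9. The medians of these lists with slide as a block were -0.95, 0.38, -0.43, -0.26 and 0.21.

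The null-against-heterozygous effect on markers of several cell types and on ER genes differed between the pairs as well. Higher and lower here compare the effect in pair 8 with that in pair 2, not the expression levels of the pairs. The effect was higher in pair 8 for 9 of 30 mesenchymal markers and lower for 1. It was higher for 9 of 22 myeloid genes and lower for 4, and higher for 4 of 13 smooth muscle markers, among them Cnn1. For basal markers it was lower in 7 of 17 cases and higher in 1. It was also lower for 7 of 22 ER genes, 2 of 10 endothelial markers and 2 of 17 luminal markers, among them Krt19. The adjusted p was 0.00144, 0.0025 and 0.0308 for the mesenchymal, myeloid and smooth muscle lists, and adjusted p = 0.219, 0.134 and 0.242 with an estimated correlation. For the basal, ER, endothelial and luminal lists it was 0.0025, 0.0452, 0.0128 and 0.0285, and adjusted p = 0.195, 0.134, 0.312 and 0.438 with an estimated correlation. Counts adjusted over the list alone were 11 mesenchymal higher and 1 lower, 10 myeloid higher and 4 lower, 4 smooth muscle higher, 8 basal lower and 1 higher, 7 ER lower and 2 higher, 2 endothelial lower and 2 luminal lower. The ER list no longer passed with slide as a block (adjusted p = 0.159), and the medians were 0.21, 0.31 and 0.23 for the first 3 lists and -0.29, -0.15, -0.32 and -0.24 for the others. The luminal median of -0.31 turned to 0.059 in the Cy3 channel alone, where the endothelial median shrank from -0.402 to -0.0969 and the mesenchymal median grew from 0.173 to 0.279.

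The single genes that differed most were Pi15 (4.94), Il6 (4.43), Slit3 (4.07), Gdf10 (3.92) and Cnn1 (3.87) on the side of pair 8, and Krt19 (-3.53), Esm1 (-3.18), Itm2a (-2.81), Adgrg6 (-2.59) and Ano1 (-2.55) on the side of pair 2. By limma, the effect differed for 3776 genes, being higher in pair 8 for 1779 and lower for 1997. This balance turned to 1977 higher and 1615 lower with the processed signals, to 1474 and 1445 with the mean over all probes and to 1292 and 997 with the deposited table. The count was 6053 with slide as a fixed block and 5907 with slide as a random block.

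The mean of the 4 lines against benign epithelium sets cultured lines beside the wild type control of the series. Luminal epithelial markers were lower in the lines in 21 of 21 cases, by a median of -5.18 log2 units, among them E-cadherin Cdh1 (-8.11, SE 0.124), the keratins Krt8 (-7.14), Krt18 (-7.12) and Krt7 (-6.26), and Rab25 (-5.54). Mesenchymal markers were higher in 24 of 30 cases, by a median of 3.42, among them the collagens Col1a1 (9.44, SE 0.052) and Col1a2 (7.79), Sparc (7.16) and Fstl1 (6.59), while Fn1 (-0.62), Tnc (-0.99) and Mmp3 (-1.23) were lower. Fibroblast markers were higher in 9 of 13 cases, including Col6a3 (7.04), Pdgfra (5.27), Ogn (5.28, at least 53.3-fold) and Lum (3.18, at least 9.34-fold). Basal markers were lower in 15 of 19 cases, including Lama3 (-4.89) and Itgb4 (-4.19), with Snai2 (2.88), Col17a1 (1.00) and Trp63 (0.48, at least 1.38-fold) higher. Camera gave adjusted p = 1.2e-13 for luminal, 4.23e-11 for mesenchymal, 2.97e-05 for fibroblast and 0.000102 for basal markers. With an estimated correlation the mesenchymal list had adjusted p = 0.0337, and the luminal, fibroblast and basal lists had adjusted p = 0.0522. The counts adjusted over the list alone were the same as over all genes for these 4 lists.

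Mitosis genes rose in 29 of 30 cases in the lines, including Kif20a (1.67) and Foxm1 (0.97), and DNA replication genes in 19 of 30, including Uhrf1 (1.02) and Mcm3 (0.93), with cyclins Ccne1 (-0.23) and Ccne2 (-0.89) lower. Glycolysis and hypoxia genes rose in 19 of 28 cases, including Egln3 (4.47) and P4ha1 (2.72), with Aldoc (-1.85), Car9 (-1.16) and Ndrg1 (-0.53) lower. The adjusted p was 2.1e-08, 0.00446 and 0.000278 in that order, and adjusted p = 0.155, 0.423 and 0.191 with an estimated correlation. In P8 by itself, the DNA replication and glycolysis lists did not pass (adjusted p = 0.0721 and 0.162). In the mean of the lines, interferon response genes fell in 16 of 26 cases, including the RNA sensor Ifih1 (-3.04) and Bst2 (-2.73), with Ifit2 (2.81), Irf1 (1.73), Ifitm3 (0.91) and Stat2 (0.27, and 0.167 with adjusted p = 0.142 in the Cy3 channel alone) higher (adjusted p = 0.00667, and adjusted p = 0.338 with an estimated correlation). Taken singly against benign epithelium, 21 of these genes were down in P8 (list adjusted p = 1.15e-05, and adjusted p = 0.109 with an estimated correlation), 19 in CaP8 (0.000134, and adjusted p = 0.185 with an estimated correlation) and 16 in P2 (0.0676), and CaP2 had 12 up and 11 down with a median of -0.025 (0.928). Immune suppression genes rose in 8 of 14 cases, including prostaglandin E synthase Ptges (4.87) and Tgfb3 (1.87), and Nt5e fell by 2.21 (adjusted p = 0.042, and adjusted p = 0.133 with an estimated correlation), and that list passed in P8 and CaP8 (0.012 and 0.0061, and adjusted p = 0.0527 and 0.0486 with an estimated correlation) and not in P2 or CaP2 (0.212 and 0.231). For these 5 lists the counts adjusted over the list alone were the same. Of 26 myeloid chemoattractants and growth factors 11 rose, including Cxcl12 (5.57), Cx3cl1 (3.87) and Il33 (3.42), and 11 fell, including Cxcl16 (-4.10), with a list adjusted p of 0.973.

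Other large rises in the lines were Serpinh1 (8.64), Cd34 (8.19), Nrn1 (7.29), Serpinf1 (7.29), Clmp (7.26, at least 283-fold) and Gas1 (7.08), and other large falls were Mal2 (-9.09), the defensin Defb14 (-7.36), Kcnk1 (-7.28), Plekhs1 (-7.25), Cldn7 (-7.09), neurotensin Nts (-6.97, at least 406-fold) and Sorbs2 (-6.92, at least 175-fold). By limma, 12445 of 20264 genes passed the threshold, 6376 up and 6069 down, and 3220 changed at least 2-fold. Falls outnumbered rises with no filter (6534 to 6424) and with the stricter filter (4815 to 4753). Benign epithelium was the only group labelled as microdissected and the only one without Cre, so tissue, culture and genotype cannot be told apart. It also lay alone on its slide, so a part played by slide cannot be removed from single values. Replicates of P8, P2 and CaP2 lay on more than 1 slide each and still correlated at 0.989 or more, so effects among those slides fall short of the whole difference. The size of an effect of the slide of benign epithelium was not measured, since no line array lay on it. Of single lines, 11160 genes differed from benign in P8, 11431 in CaP8, 12562 in P2 and 11805 in CaP2. On probe A_51_P275350 the log2 difference of Pten from benign epithelium was -1.15 in P8, -1.57 in CaP8, -0.50 in P2 and -0.90 in CaP2. Probe A_52_P24843 gave -1.25, -1.78, -1.33 and -1.63 in the same order, and A_52_P121155 gave -0.61, -0.82, -0.64 and -0.90. The order of the lines across pairs thus depends on the probe.

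**Figure D3:**
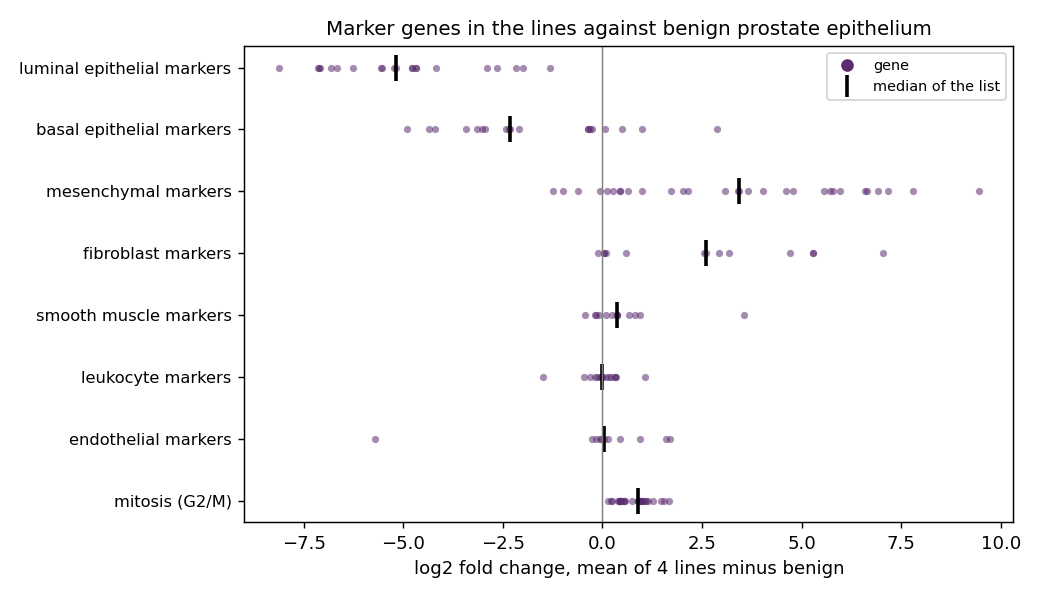
Log2 fold change of each measured member of 8 fixed lists, mean of 4 lines minus benign epithelium. Each point is a gene and each black bar the list's median. The luminal median is -5.18 and the mesenchymal median 3.42.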

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

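Of the tests in this part, the comparison of the cholesterol list between pairs was chosen after its result was seen. All values below were singled out because a test of the difference itself, CaP8 minus P8 less CaP2 minus P2 in limma, passed the threshold. A positive value means that the null line was relatively higher in pair 8. The count of such genes was 3776.

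The null-against-heterozygous effect on cholesterol synthesis genes was higher in pair 2, with differences for Hmgcs1 (-1.42), Msmo1 (-1.33), Fdps (-1.15), Tm7sf2 (-1.99) and Ldlr (-0.90). The pattern that called for weighing is their joint difference between CaP2 and P2, and against benign epithelium the list's median was -0.678 in P2, with 20 of 25 genes lower, and 0.19 in CaP2, 0.229 in P8 and 0.344 in CaP8. A slide effect is argued against by the list's median of 0.877 within slide 5, where P2 and CaP2 arrays lie side by side, and an effect of the reference channel by the median of 0.876 in Cy3 alone. Pten state alone, acting alike in every line, is argued against by the median of -0.0759 in CaP8 against P8. A difference between these lines other than Pten, or in their culture at harvest, could account for the pattern and was not tested, since each genotype has 1 line per pair.

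Metabolic and secretory genes that differed were Bnip3 (-0.40), Pdk1 (-1.08), Egln1 (-0.65), Ankrd37 (-0.85), Adm (1.74) and Pdia6 (-0.74). Interferon and antigen presentation genes that differed were Isg15 (-1.62), Ifit3 (-1.02), Oasl2 (-1.18), Ifitm3 (0.75), Isg20 (-1.98), Tap1 (0.97), Tap2 (0.87), H2-K1 (-0.59), H2-T23 (-0.40), H2-M9 (3.76) and Calr (-0.60). Signalling and inflammatory genes that differed were Il6 (4.43), Il34 (-1.49), Ptgs2 (1.79), Cxcl12 (0.40), Saa3 (1.63), Lgals9 (0.65) and Cck (-1.87). Immediate early genes that differed were Ccn1 (-0.56), Ccn2 (-1.66), Atf3 (0.53) and Klf4 (-0.57). P53, FOXO and mitosis genes that differed were Trp53inp1 (1.08), Cdkn1a (0.46), Plk2 (-0.39), Pmaip1 (0.92), Fas (0.86), Bbc3 (-0.39), Gadd45a (0.74), Sesn3 (-0.33), Ccnb1 (0.63) and Aurka (0.24).

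Matrix, muscle and fibroblast genes that differed were Mmp2 (1.18), Postn (-0.70), Tnc (1.82), Aspn (-1.57), Dpt (-1.62), Dcn (1.67), Mfap5 (2.34), Fbln1 (1.09), Lum (-1.08), Cnn1 (3.87), Tagln (2.90), Sfrp1 (3.16), Slit3 (4.07), Ccbe1 (1.32) and Adamts3 (2.75). Epithelial genes that differed were Krt19 (-3.53), Krt33a (1.63), Cd24a (-1.15), Lamc2 (-1.02), Itgb4 (-0.43), Snai2 (0.77), Lce1i (3.46) and Crabp2 (1.03).

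Other named genes that differed were Ostn (3.26), Nefl (2.38), Hba-a1 (1.27), As3mt (1.71), Avil (1.44), Brinp3 (1.34), Kcnab1 (-0.66), Pi15 (4.94), Syt13 (3), Spry3 (2.56), Esm1 (-3.18), Itm2a (-2.81), Cbr2 (-2.17), Crip1 (-2.38), Car8 (-2.19), Hopx (-1.43), Gdf10 (3.92), Akr1c18 (3.74), Npy1r (2.86), Adgrg6 (-2.59) and Ano1 (-2.55).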

How the results depend on the processing

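Of the alternatives in this part, those without genes at the reference floor, within 1 slide and without CaP2 replicate 1 and P2 replicate 3 were chosen after seeing the data. Counts of genes stayed within 1.5 times of the reported ones except as follows. With the deposited value table, which holds fewer genes, they were 1791 for CaP8 against P8, 4432 for CaP2 against P2, 4291 for the mean of both pairs, 2289 for the difference between pairs, 7664 for the lines against benign, 6844 for P8, 7174 for CaP8, 7117 for P2 and 7267 for CaP2. With slide as a random block, CaP8 against P8 had 5190 and the difference 5907, with slide as a fixed block 5868 and 6053, and within slide 3 alone CaP8 against P8 had 5597, against 2736 and 3776 as reported; the cause was not tested. Leaving out 1 array at a time gave 1582 to 2467 for CaP8 against P8, lowest without CaP8 replicate 2, with 1784 and 1647 without CaP8 replicates 1 and 3. Without CaP2 replicate 1 and P2 replicate 3 together, CaP2 against P2 had 6195.

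Over 233 results for named genes, 5395 of 5508 alternative values kept direction and side of the threshold, 99 kept direction only, 2 newly passed and 12 changed sign. Csf1 in CaP8 against P8 was -0.624 in Cy3 alone and -0.024 to 0.066 when 1 array was left out. In the mean of both pairs, Csf1 was 0.031 with processed signals, 0.031 in the deposited table and -0.054 to 0.011 when 1 array was left out, and its difference between pairs was -0.109 in Cy3 alone. Egln1 in CaP8 against P8 was 0.074 as the mean over probes. The difference between pairs for Pten was 0.008 with slide as a fixed block, 0 without CaP2 replicate 1 and P2 replicate 3, and -0.085 to 0.022 when 1 array was left out. Of the values that changed sign, that of Csf1 in CaP8 against P8 in Cy3 alone passed the threshold. Egln1 passed as reported, but its value of changed sign did not. The other values that changed sign were not past the threshold. The cause was not tested.

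With slide as a block, lists that newly passed were DNA replication in CaP8 against P8 (adjusted p = 0.0336) and, in the difference between pairs, immune suppression (0.0384) and reference pool tissues (0.0368). In the mean of both pairs, the basal and mitosis lists (0.0177 and 0.00204) did not pass with it (0.127 and 0.128), nor with an estimated correlation (0.352 and 0.115). Without CaP2 replicate 1 and P2 replicate 3, the median in CaP2 against P2 was -0.0497 for the myeloid list (from -0.242) and 0.242 for MHC class I (from 0.38), and in the difference between pairs -0.13 for luminal (from -0.306), -0.235 for endothelial (from -0.402) and 0.105 for smooth muscle markers (from 0.164). With the replicate number as a block, the counts in the same order were 2591, 7125, 6677, 3708, 12432, 11181, 11452, 12516 and 11820. Same-numbered arrays did not deviate together: correlations of their deviations ran from -0.354 to 0.241 and not every array matched its own number best. Processed signals moved the median of all genes to 0.111 in P2 and 0.118 in CaP2 against benign, from -0.0313 and -0.0105. Dim signal limits the lists: 54.6 to 72.1% of spots were well above background in Cy3.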

Other observations

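Of the tests in this part, those on the fixed share of light and on the Pten signal were chosen after the result was seen. The test on the fixed share first took the lower ratio of the 2 directions, 0.718, which met its prediction, and its rule was changed after that run to ask for both directions, which left it undecided.

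The lists of smooth muscle, leukocyte, endothelial, erythroid, seminal vesicle and reference pool tissue markers did not pass by camera within either pair, although the endothelial list (adjusted p = 0.0128, 0.0429 with slide as a block and 0.312 with an estimated correlation) and the smooth muscle list (0.0308, 0.0484 and 0.242) passed by camera in the difference between pairs. In CaP2 against P2, 4 of 13 smooth muscle markers fell and 2 rose, with a list adjusted p of 0.273 by camera, and Cnn1 and Tagln led the falls. FOXO targets had 5 of 16 down and 1 up in CaP2 against P2 (list adjusted p = 0.147), with Gadd45a at -0.89 and Sesn3 at 0.65, and 3 up and 3 down in CaP8 against P8 (0.673). Leukocyte markers had 1 of 16 up in each pair (adjusted p = 0.537 and 0.477), and endothelial markers had 1 of 10 up and 1 down in CaP8 (0.618) and 2 up in CaP2 (0.145). Erythroid markers had 1 of 4 up in each pair, and in CaP8 that gene was Hba-a1. Reference pool tissue markers had none of 18 past the threshold in CaP8 against P8 and 1 in CaP2 against P2, and seminal vesicle genes none of 8 and 1. Androgen response and prostate secretion genes had 1 of 23 up and 2 down in CaP8 against P8 (0.841) and 4 up and 3 down in CaP2 against P2 (0.503).

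Against benign epithelium, androgen response and prostate secretion genes were lower in the lines in 8 of 24 cases, including Hoxb13 (-4.49) and Tmprss2 (-3.92), and higher in 3, with a list adjusted p of 0.0592 by camera in the mean of the lines, 0.0058 in P2 and 0.0315 in CaP2 (0.34 and 0.526 with an estimated correlation), 0.171 in P8 and 0.268 in CaP8. Immediate early genes were lower in 13 of 22 cases, including Ccn2 (-2.91) and Dusp1 (-2.72), and Jun rose by 1.41 (list adjusted p = 0.171). P53 targets were lower in 9 of 20 cases, led by Pmaip1 (-3.33), with a list adjusted p of 0.163 in the mean of the lines and 0.00139 in CaP2, where 15 were lower. In the mean of the lines, cholesterol synthesis genes were higher in 10 of 25 cases and lower in 11, and in single lines 20 were lower and 2 higher in P2, 14 higher and 6 lower in P8, 13 higher and 6 lower in CaP8, and 13 higher and 7 lower in CaP2. ER chaperone genes were higher in 11 of 22 and lower in 9 in the mean of the lines, and passed in CaP2 (12 higher, 3 lower, adjusted p = 0.0254, and 0.323 with an estimated correlation). Hyou1 and Sel1l of this list had probes that passed in opposite directions in the mean of the lines. So did 358 of 6906 genes with several probes there, 98 of 6779 in CaP2 against P2 and 4 of 6779 in CaP8 against P8. Leukocyte markers were mixed, with Cd68 at -1.50.

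Pten signal stayed well above background in the lines labelled Pten null. Compression by the reference channel is argued against, since the larger of the falls in Cy3 alone was -0.489 log2 units. The 3 Pten probes kept between 69.4 and 86.3% of the heterozygous signal. Probes outside the deleted part of the gene and cells with an intact Pten gene in the lines labelled null cannot be told apart from these values. The deleted part is not given, so the probes cannot be placed relative to it. Either could leave this signal, and a stable transcript without the deleted part is a further untested candidate explanation.

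The reference channel, which should hold the same pool on every array, was often brighter where the sample channel was brighter. Among probes at least 16-fold apart in Cy3 between every benign and every line array, the median share of the Cy3 difference seen in Cy5 was 0.0104 (207 probes, benign brighter) and 0.0559 (312 probes, lines brighter) in processed signals. In signals less the local background, where the pattern was noticed, the shares were larger, 0.094 (146 probes) and 0.0893 (166 probes), so the size depends on the measure. Over all probes, the median log2 change of Cy5 from benign to the lines was 0.395 in processed signals and 0.128 in background-subtracted ones. The shares were not corrected for this offset, which lowers the share where benign was brighter and raises it where the lines were brighter. For the chosen probes in processed signals, the median log2 change of Cy5 towards the brighter side was 0.19 (benign brighter) and 0.949 (lines brighter). A fixed share of Cy3 light read in the Cy5 channel would vary between probes no more than between arrays. The ratio of these spreads was 0.718 and 1.68, so that 1 direction met the prediction and the other neither met nor excluded it. In background-subtracted signals the ratios of 1.14 and 0.296 both met it. The ratio of 0.296 came with a spread of 0.604 between arrays and 0.179 between probes, so noise between arrays alone could meet the prediction there. A pool that differed between slides would leave no share within slide 5, where probes at least 4-fold apart in Cy3 were used. The median there was 0.0249 in processed signals and 0.061 in background-subtracted ones, values on either side of what would exclude it. In the latter signals it was 0.0244 where P2 was brighter and 0.138 where CaP2 was brighter. Both explanations therefore remain open, and ratios of bright genes such as Csf1 may understate differences between samples.

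Other splits of the same arrays were counted for each comparison. For the pairs and for each line against benign, 3 arrays against 3 give 10 splits, too few for a share under 0.05. There, CaP8 against P8 had 2736 genes and the highest other split 0, CaP2 against P2 had 7198 and 0, P8 against benign 11160 and 5, CaP8 against benign 11431 and 0, P2 against benign 12562 and 0, and CaP2 against benign 11805 and 0, and in each only 1 of the 10, the real one, reached the real count. For the mean of both pairs, 1 of 100 splits, the real one, reached the real count (6732, highest other 4290). The same held for the lines against benign (12445, highest other 4439, 1 of 100). Other splits place arrays of different lines or of tissue and lines in 1 group, which widens its spread. The real split is thereby favoured, so chance between lines, animals or slides cannot be excluded. For the difference between pairs 4 of 100 splits gave 3776 or more. The highest, 6732, exchanges P2 and CaP2 and is the mean of both pairs, so it points to a structure of the samples. These splits carry the effects within the pairs, so they leave open whether chance is excluded for the difference.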
